A study of Caenorhabditis elegans with 22 samples.

How the data were processed

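Whole N2 worms were sequenced as polyA libraries made with the Kapa mRNA HyperPrep kit. The deposited table holds whole-number read counts per gene for 22 libraries, 1 column each, with no column left unassigned. Per the submitters' processing notes, the authors used Trimmomatic 0.39, fastp 0.23.2, STAR 2.7.9a, featureCounts and Subread 2.0.3 with genome build ce10. The gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Genes are named by the symbols of the deposited table, and no coordinates are given, since the reference used here for names and exon lengths is WBcel235. Counts of near-identical genes (the hsp-16 family, vitellogenins, major sperm proteins and their relatives, histones, and clustered UDP-glucuronosyltransferase and cytochrome P450 genes) and of overlapping or antisense genes are uncertain for that reason.

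Group, ethanol concentration, time and replicate number were taken from the labels, which call the libraries biological replicates. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries. No 2 libraries of a group held identical values, and chi-square per degree of freedom between group mates ran from 2.07 to 126.2, so each counted as 1 replicate. Of 42048 genes, 23391 had counts and 15310 passed edgeR's filterByExpr over the 7 groups (minimum count 10, minimum total 15), which kept 99.9% of counts. CPM values given as mean ± SD were computed from the deposited counts with library sizes multiplied by their TMM factors.

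edgeR 4.0.16 (R 4.3.3) was fitted to all 22 libraries with 1 mean per group, TMM factors, robust quasi-likelihood dispersions and two-sided F-tests. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and every adjusted p given for a gene is from this test unless another tool is named. Ethanol was compared with the control of the same time, and each group with time zero. Differences of the ethanol effect between times were tested with 2 degrees of freedom and for each pair of times. SE of a log2 fold change was its size divided by the square root of F. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 40 lists and 3 times. With an estimated correlation, 1 list call held at 1 h, 0 at 4 h and 0 at 20 h. Of 42 lists written, the intracellular pathogen response and the mitochondrial genome transcripts had 0 members measured and were not analysed here. For the overlap of calls between comparisons with shared time zero libraries, 20 simulations of unchanged groups and 6 splits of the time zero libraries were made. For the overlap of ethanol calls with changes from time zero, 8 simulations of unchanged groups were fitted at each time. Loadings of the oocyte and eggshell, spermatogenesis and DNA replication lists on the main axis within groups were set against 10000 random lists matched on mean expression, after a trend on exon length was taken out, a test chosen after the data were seen.

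The design, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, apart from those said to be chosen later. The rule took, for each ethanol comparison, the 6 largest rises and 6 largest falls among genes past the threshold with all ethanol libraries on the same side of all controls, a mean of at least 5 CPM and at least 10 counts in each group. It added 15 genes named at every time and, for each list past its threshold, the 2 members with the largest change not yet named. For control against time zero it took 4 rises and 4 falls. Genes under 10 counts in a group are given as a number, with at most 2 named. A fold against a group with no counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% interval. Such floors and intervals cover counting error alone.

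The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other count filters, only the groups compared, a replicate block, a minimum log2 fold change of 1, each library left out in turn, and for the lists an estimated correlation and fry. Those chosen after the data were seen left out the 6 libraries with scores above 10 on the main axis within groups, left out in each group the library farthest from the median score where it lay over 10 away (6 libraries), added each library's slope on exon length as a covariate, or left out embryo and cuticle genes. The slope was estimated from the same data, on deviations from the group means. It therefore took out spread within groups and could not correct a length trend between groups. Across genes, Spearman's rho of the ethanol log2 fold change with log2 exon length was -0.229 at 1 h, -0.0786 at 4 h and -0.200 at 20 h. Library totals were 10908205 to 15302047 counts, and group mates differed by more than counting error, so both depth and the spread between libraries bear on the precision. The tests were tested on simulated data with 198 or 199 changed genes. At fold changes of 1.5, 2 and 4, edgeR recovered 5.97%, 40.9% and 80% of them for 1 h (14956 genes), 2.99%, 41.8% and 87.7% for 4 h (14959 genes), and 8.96%, 50% and 81.5% for 20 h (14962 genes). False calls made up 7.78%, 2.25% and 9.80% of its calls, above the nominal share at 1 and 20 h, and for the test between times 9.09%, 5.36% and 5.09%. A list raised by simulation was called at all 3 times, with 0 other lists. The simulated changed genes were fewer than the 1021, 4664 and 8142 called at 1, 4 and 20 h. The Benjamini-Hochberg cutoff depends on the share of changed genes, so the recovery does not carry over to the real comparisons. Genes were simulated independently of each other, without the main axis within groups. In the real libraries the estimated correlation between members was 0.302 for the spermatogenesis list and 0.405 for the oocyte and eggshell list. The simulation therefore does not show how often lists of correlated genes are called in error. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.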

Results

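Gene expression was measured by polyA RNA sequencing of whole Caenorhabditis elegans of the N2 laboratory strain, to ask how exposure to ethanol in liquid changes transcript levels over a day. Worms grown in synchrony on bacterial plates were moved to S-basal, a salt buffer without food, holding either 0% or 5% (v/v) ethanol, and were collected after 1, 4 or 20 h at 20 °C. The 22 libraries fell into 7 groups, with 4 libraries at time zero and 3 in each of the other 6 groups. Library totals ran from 10908205 counts (control replicate 1 at 4 h) to 15302047 counts (ethanol replicate 3 at 20 h). Of 42048 genes in the table, 15310 had enough counts to be tested. Along the main axis of variation within groups, which held 41.4% of the within-group variance, 6 libraries had scores above 10. They were replicate 1 at time zero, replicate 2 of the control and of ethanol at 1 h, ethanol replicate 2 at 4 h, and control replicate 1 and ethanol replicate 3 at 20 h. On the other side of the axis 8 libraries lay more than 10 from 0. Among the 1 h controls replicate 1 (score -41.6) was farther from the middle library, replicate 3 (6.20), than replicate 2 was (35.4). Rises and falls with ethanol are given relative to the 0% control of the same time, which itself moved from time zero. The protocols call the worms L3 larvae and the series title calls them L4. Transcripts of adult-stage genes were abundant at time zero, where the yolk protein gene vit-2 stood at 15740 ± 2989 CPM (counts scaled to the TMM-adjusted library size, SD, n = 4).

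After 1 h in 5% ethanol, the largest rises over the 0% control of the same time, among genes with at least 10 counts in each group and a mean of at least 5 CPM, included 2 UDP-glucuronosyltransferase genes. ugt-16 and ugt-8, whose products attach sugar acids to foreign compounds, were higher by a log2 fold change of 7.25 ± 0.48 (SE) and 4.67 ± 0.24. The cytochrome P450 gene cyp-13A12 rose by 5.25 ± 0.26, from 0.871 ± 0.309 CPM in the control to 32.55 ± 5.86 CPM (SD, n = 3). Other large rises were those of gba-2, a predicted glucosylceramidase (6.77 ± 0.20), pgp-1, an ABC transporter of the P-glycoprotein family (5.99 ± 0.55), and nhr-62, a nuclear hormone receptor (4.93 ± 0.17). gpdh-1, a glycerol-3-phosphate dehydrogenase that serves glycerol synthesis, had a log2 fold change of 4.42 ± 0.33. It was at 10.46 ± 0.761 CPM at time zero (SD, n = 4), 1.202 ± 0.335 in the control and 25.2 ± 2.97 in ethanol (SD, n = 3). Likewise ugt-16 was at 14.87 ± 2.72, 1.656 ± 0.376 and 258.1 ± 36.45 CPM, so both were lower in the control than at time zero. Under the same limits, the genes lowest against the control were the cytochrome P450 gene cyp-34A2 (log2 fold change -3.64 ± 0.25), ZK550.2 (-2.85 ± 0.42), the thaumatin family gene thn-2 (-2.83 ± 0.36), scl-2 (-2.82 ± 0.28), Y70C5A.3 (-2.67 ± 0.53) and math-24 (-2.42 ± 0.39). Of these 6 genes, cyp-34A2, ZK550.2, thn-2 and scl-2 had risen from time zero in the control. cyp-34A2 was at 1.96 ± 0.332 CPM at time zero (SD, n = 4), 16.01 ± 1.99 in the control and 1.27 ± 0.169 in ethanol (SD, n = 3). In the same order ZK550.2 was at 13.68 ± 1.06, 57.02 ± 3.53 and 7.895 ± 1.68 CPM, thn-2 at 11.096 ± 0.647, 83.6 ± 10.02 and 11.72 ± 0.910 CPM, and scl-2 at 12.52 ± 1.555, 102.7 ± 8.41 and 14.5 ± 1.88 CPM. The largest adjusted p among these 13 genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was 0.00235, for Y70C5A.3. In all, 1021 genes passed the threshold at 1 h, of which 757 were higher and 264 lower in ethanol. With each library's slope on exon length as a covariate, an alternative chosen after seeing the data and estimated from it, 1669 were higher and 1909 lower. All 3 ethanol libraries lay on the same side of all 3 controls for 18.9% of genes, where chance gives 10%. Of the genes called, 94 had under 10 counts in a group, among them nas-3, at least 18.01-fold higher.

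Among the 40 gene lists tested, 8 passed camera's threshold at 1 h. Of 65 cytochrome P450 genes, 25 were higher and 2 lower (32 and 3 adjusted over the list alone), and this was the list whose call held with an estimated correlation (adjusted p = 0.0294). cyp-13A8 was at 26.6 ± 5.54 CPM in ethanol against 0.108 ± 0.114 CPM, a count ratio of 295.6 (95% interval 100.8 to 1436), and cyp-35A1 had a ratio of 39.9 (6.80 to 1609). Of 62 UDP-glucuronosyltransferase genes, 23 were higher and 2 lower (29 and 3 adjusted over the list alone), with adjusted p = 0.133 with an estimated correlation. ugt-10 had a count ratio of 50.1 (13.5 to 418.3), and ugt-34, with no counts in the controls, was at least 22.1-fold higher against a floor of 3 counts over the group. In the metal response list 6 of 11 members were higher (8 adjusted over the list alone; adjusted p = 0.102 with an estimated correlation). Among them were the cadmium-responsive genes cdr-2 (2.22 ± 0.32) and cdr-4 (1.58 ± 0.34). Of 43 glutathione S-transferase genes 7 were higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). Largest were the rises of gst-33 (4.05 ± 0.29) and gst-9 (2.204 ± 0.373). Of 21 genes of the unfolded protein response of the endoplasmic reticulum 6 were higher (7 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). Members higher included the transcription factor gene xbp-1 (1.23 ± 0.16) and the protein disulfide isomerase gene pdi-6 (0.96 ± 0.13).

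The other 3 lists past camera's threshold at 1 h lay lower in ethanol without any member passing the test by itself, over all genes or adjusted over the list alone. They were spermatogenesis (53 members, median log2 fold change -0.19), DNA replication and cell cycle (25 members, -0.41) and oocyte and eggshell (15 members, -0.52), and with an estimated correlation their adjusted p values were 0.806, 0.683 and 0.707, and with fry 0.292, 0.119 and 0.21. For each of the 3 lists the median loading on the main axis within groups, after a trend on exon length was taken out, lay at percentile 100 of 10000 random lists matched on mean expression, in a test chosen after seeing the data. Along that axis the 1 h controls had scores of -41.6, 35.4 and 6.20 and the ethanol libraries -29.02, 46.8 and -17.8. The eggshell gene cpg-1, named after its values were seen, was at 890.9 ± 812.2 CPM in ethanol and 1446 ± 933 in the control (SD, n = 3) and did not pass the test (adjusted p = 0.688). Without control replicate 2 the oocyte list had adjusted p = 0.194 and the DNA replication list 0.0932. Without ethanol replicate 1 the spermatogenesis, oocyte and DNA replication lists had adjusted p = 0.191, 0.191 and 0.0795, without control replicate 3 the spermatogenesis and oocyte lists had 0.0535 and 0.0722, and without ethanol replicate 3 the oocyte list had 0.095. The list of the unfolded protein response had adjusted p = 0.128 without control replicate 1 and 0.081 without ethanol replicate 2. Without the library farthest from its group's median score in each of 6 groups, an alternative chosen after seeing the data, it had 0.852.

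Of the 15 genes named at every time whatever their result, the alcohol dehydrogenase gene sodh-1 (-1.01 ± 0.19), the acyl-CoA synthetase gene acs-2 (-1.63 ± 0.38) and the glyoxylate cycle gene icl-1 (-1.37 ± 0.24) were lower in ethanol than in the control at 1 h, while the metallothionein gene mtl-1 (1.91 ± 0.40) and the antimicrobial peptide gene nlp-29 (1.16 ± 0.31) rose with gpdh-1. The chaperone genes did not pass the test at 1 h, with log2 fold changes of 0.79 ± 0.97 for hsp-16.2, 1.56 ± 0.94 for hsp-70, 0.64 ± 0.21 for hsp-4 and -0.04 ± 0.39 for hsp-6. With only the 1 h libraries in the fit hsp-70, at 12.7 ± 0.803 CPM in ethanol and 4.31 ± 0.105 in the control, passed (adjusted p = 0.00204). The remaining members that did not pass were alh-1 (-0.14 ± 0.15), gst-4 (0.61 ± 0.23), gcs-1 (-0.13 ± 0.24), sod-3 (0.34 ± 0.22) and fat-7 (0.23 ± 0.35). The call of acs-2 ended without ethanol replicate 1 (adjusted p = 0.06), and that of nlp-29 without control replicate 2 (0.0876), control replicate 3 (0.144), ethanol replicate 1 (0.108) or ethanol replicate 3 (0.0865). Conversely hsp-4 passed with DESeq2 (0.0389), library sizes alone (0.00608), upper-quartile factors (0.0269) and without control replicate 2 (0.0106), and gst-4 passed without ethanol replicate 2 (0.0422). Both also passed without the 6 libraries with scores above 10 (0.00318 and 0.0335) and with the length slope covariate (0.000169 and 0.00232). Without the library farthest from its group median, hsp-6 (-0.87, adjusted p = 0.0012), alh-1 (-0.33, 0.0055), gst-4 (1.00, 0.000143) and gcs-1 (-0.60, 0.00036) passed. With limma-voom mtl-1 had adjusted p = 0.0703, and with only the 1 h libraries in the fit icl-1 had 0.0582. In that fit 620 genes were called (470 higher, 150 lower), without the 6 libraries with scores above 10 1550 (523 lower) and without the library farthest from its group median 6715 (3187 higher, 3528 lower). The last left the 1 h controls with scores of 35.4 and 6.20 and the ethanol libraries with -29.02 and -17.8, so that their group means moved apart along the axis. The 264 lower calls became 171, 165 and 153 without control replicate 2, control replicate 3 or ethanol replicate 3.

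**Figure D1:**
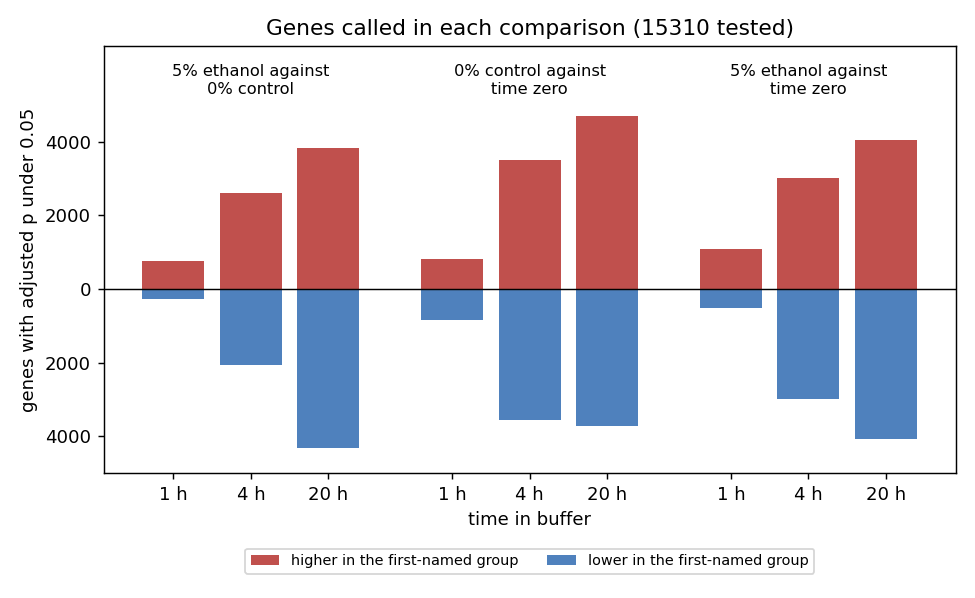
Number of genes with adjusted p under 0.05 (y axis, higher above 0 and lower below 0) in the 9 comparisons, by hours in buffer (x axis). The comparison of 5% with 0% ethanol rose from 1021 genes at 1 h to 4664 at 4 h and 8142 at 20 h, and 0% ethanol against time zero from 1657 to 7068 and 8442. With only the groups compared in the fit these were 620, 6515 and 6045, and 1584, 8063 and 7121, so the order of 4 and 20 h depends on the fit.

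After 4 h, among genes with at least 10 counts in each group and a mean of at least 5 CPM, gba-2 and fmo-2 had the largest rises over the control. gba-2 was at 0.295 ± 0.104 CPM in the control and 519 ± 45.8 CPM in ethanol (SD, n = 3), a log2 fold change of 10.72 ± 0.25. fmo-2, a flavin-containing monooxygenase gene, was at 0.347 ± 0.135 and 290 ± 28.8 CPM (9.67 ± 0.54). ugt-33 (8.52 ± 0.41), cyp-13A12 (8.38 ± 0.30), the C-type lectin gene clec-210 (7.99 ± 0.31) and F08G2.5 (7.81 ± 0.42) completed the 6 largest rises under these limits. The 6 genes lowest against the control under the same limits were the cytochrome P450 genes cyp-37B1 (-6.50 ± 0.43) and cyp-34A2 (-6.48 ± 0.28), C48B4.1 (-5.12 ± 0.31), the carnitine palmitoyltransferase gene cpt-4 (-4.84 ± 0.43), F11F1.1 (-4.71 ± 0.38) and scl-2 (-4.48 ± 0.29). The largest adjusted p of these 12 genes was 2.26e-08. In all, 4664 genes passed at 4 h, 2612 higher and 2052 lower. The libraries of the 2 groups were separate for 54.3% of genes, where chance gives 10%. Of the genes called, 524 had under 10 counts in a group, among them lips-11, at 21.65 ± 1.21 CPM in ethanol with no counts in the controls and at least 289.9-fold higher.

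The list of the unfolded protein response of the endoplasmic reticulum had 16 of 21 members higher and none lower at 4 h (19 higher adjusted over the list alone), with a median log2 fold change of 1.54 and adjusted p = 0.168 with an estimated correlation. The choline kinase gene ckb-2 rose from 30.4 ± 2.18 to 912 ± 67.6 CPM (4.90 ± 0.23), pdi-6 by 3.59 ± 0.14, and hsp-4, which encodes the chaperone BiP, from 218 ± 7.41 to 1640.2 ± 114 CPM (2.91 ± 0.23). Cytochrome P450 genes were higher for 36 and lower for 10 of 65 (38 and 11 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation). cyp-13A8 rose from 0.127 ± 0.111 to 241 ± 2.53 CPM (10.82 ± 0.51), and cyp-35A1, with no counts in the controls, was at least 72.2-fold higher. UDP-glucuronosyltransferase genes were higher for 28 and lower for 10 of 62 (30 and 10 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). ugt-14 was at 6.19 ± 0.29 and ugt-16 at 5.93 ± 0.43. Glutathione S-transferase genes were higher for 19 and lower for 8 of 43 (20 and 9 adjusted over the list alone; adjusted p = 0.707 with an estimated correlation). gst-33 was at 4.90 ± 0.28 and gst-37 at a count ratio of 29.8 (9.86 to 147.1).

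Of 53 spermatogenesis genes, 31 were higher in ethanol at 4 h and none lower (34 higher adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). Among them were ssp-31 (1.098 ± 0.241) and spe-42 (1.095 ± 0.410). Antimicrobial peptide genes were higher for 10 and lower for 1 of 17 (10 and 2 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). nlp-29 was at 3.40 ± 0.35, cnc-2 at 2.82 ± 0.33 and nlp-30 at 2.67 ± 0.50. The median of that list was 1.51, and 1.47 with its member at 0 counts set to its bound. In the cytosolic heat shock list 3 of 11 members were higher (3 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). They were hsp-70 (4.57 ± 1.23) and the DnaJ family genes dnj-12 (0.40 ± 0.09) and dnj-19 (0.33 ± 0.11). hsp-70 was at 8.96 ± 0.741 CPM at time zero (SD, n = 4), 0.453 ± 0.156 in the control and 10.9 ± 2.22 in ethanol (SD, n = 3). C-type lectin and lysozyme genes were higher for 14 and lower for 40 of 144 (16 and 41 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). The lectin genes clec-28 and clec-25 had no counts in the 3 ethanol libraries, against 0.888 ± 0.303 and 0.806 ± 0.139 CPM in the controls, and were at least 11.6-fold and 10.6-fold lower. Fatty acid breakdown genes were higher for 9 and lower for 23 of 45 (9 and 23 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). ech-9, of the enoyl-CoA hydratase family, was lower by 7.21 ± 0.79 and the lipase gene lipl-6 higher by 4.82 ± 0.44. ech-9 was at 0.526 ± 0.238 CPM at time zero (SD, n = 4), 23.6 ± 1.62 in the control and 0.153 ± 0.148 in ethanol (SD, n = 3). In the same libraries early zygotic genes of the embryo were lower in ethanol for 25 and higher for 2 of 32 (adjusted p = 0.00295 with an estimated correlation). Genes of mid and late embryos were higher for 8 and lower for 1 of 19 (0.0799). Both lists were chosen after seeing the data and were adjusted apart from the other lists, over fewer tests.

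At 4 h sodh-1 (-3.28 ± 0.20) and icl-1 (-2.97 ± 0.25) were lower in ethanol than in the control, sodh-1 at 55.8 ± 7.47 against 542.9 ± 56.6 CPM (SD, n = 3). acs-2 (2.72 ± 0.41), gst-4 (2.40 ± 0.26) and the manganese superoxide dismutase gene sod-3 (1.13 ± 0.27) were higher than in the control. At time zero (SD, n = 4), in the 4 h control and in ethanol (SD, n = 3), gst-4 was at 39.2 ± 7.86, 2.78 ± 0.406 and 14.7 ± 2.45 CPM. In that order sod-3 was at 4.295 ± 0.520, 0.743 ± 0.153 and 1.64 ± 0.0931 CPM, and acs-2 at 30.55 ± 3.72, 6.22 ± 1.42 and 41.2 ± 3.76 CPM. gst-4 and sod-3 were thus below time zero in ethanol as well. hsp-16.2 (2.83 ± 1.21), hsp-6 (0.65 ± 0.39), gpdh-1 (0.59 ± 0.49), fat-7 (0.81 ± 0.35), alh-1 (-0.23 ± 0.15), gcs-1 (-0.14 ± 0.24) and mtl-1 (-0.03 ± 0.27) did not pass the test at 4 h. With only the 4 h libraries in the fit hsp-16.2 (adjusted p = 1.47e-05), hsp-6 (4.32e-05) and fat-7 (5.93e-05) passed, and with DESeq2 hsp-16.2 did (0.018). hsp-6, fat-7, alh-1 and gcs-1 passed without the 6 libraries with scores above 10 (0.0497, 0.0466, 0.018 and 0.0362) and without the library farthest from its group median (0.00913, 0.0445, 0.00544 and 0.00775). hsp-6 and fat-7 also passed with the length slope covariate (0.000397 and 0.0132). The call of spe-42 ended without any of the 6 libraries of that time (adjusted p from 0.0524 to 0.214). It also ended with limma-voom (0.0655), RLE factors (0.0535), library sizes alone (0.0565), upper-quartile factors (0.0531) and no low-count filter (0.0763). dnj-19 had 0.142 with no low-count filter and 0.126 without ethanol replicate 3. The other libraries whose removal ended its call were control replicate 1 (0.103), control replicate 2 (0.0983), control replicate 3 (0.0727) and ethanol replicate 2 (0.0804). limma-voom ended that of hsp-70 (0.0922). The heat shock list missed the threshold without control replicate 1 (0.0584), control replicate 2 (0.0526), control replicate 3 (0.057) or ethanol replicate 2 (0.0958). The antimicrobial list missed it without ethanol replicate 1 (0.0514) and with the length slope covariate (0.06), as the C-type lectin list did with that covariate (0.06).

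**Figure D2:**
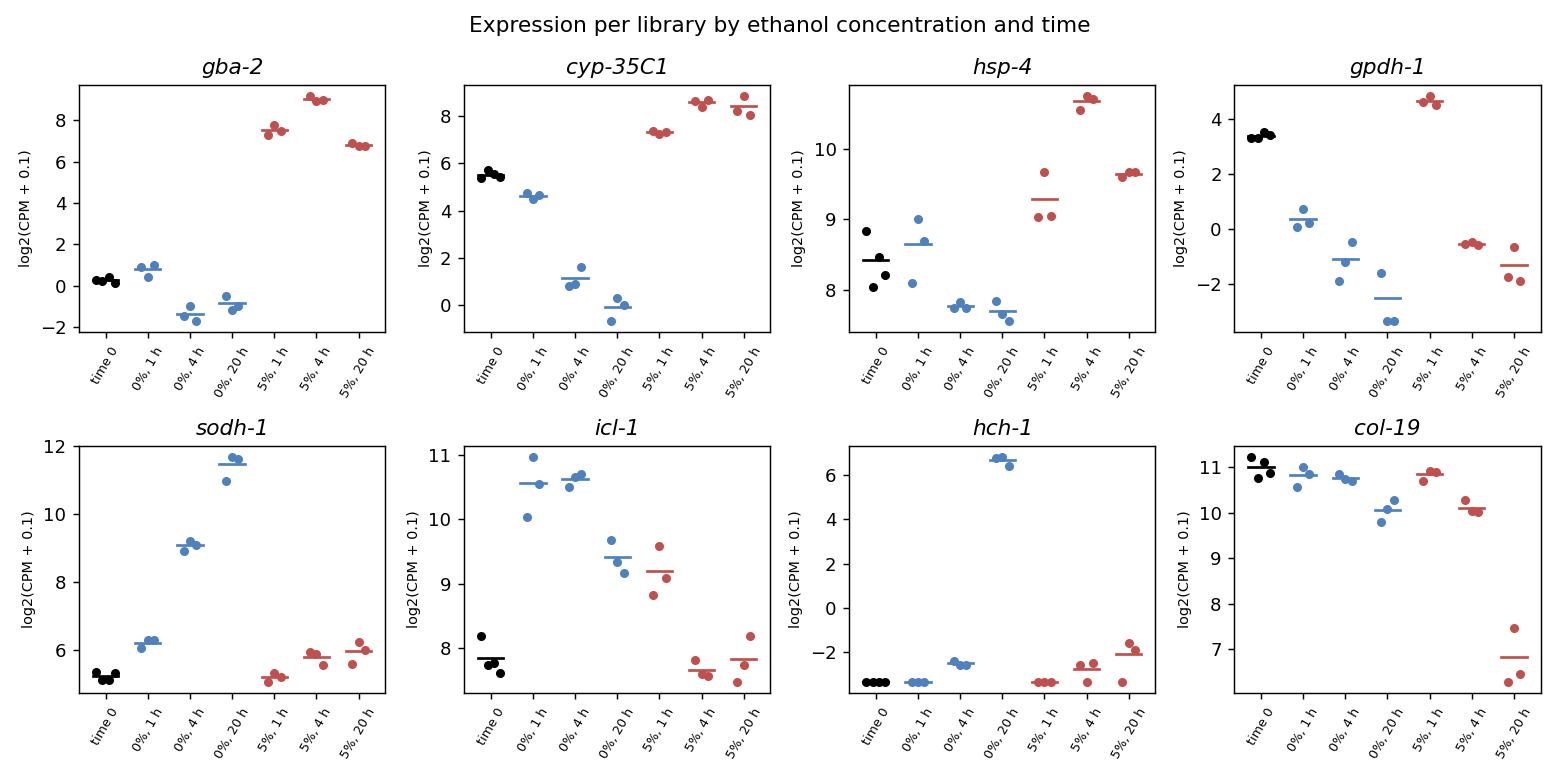
Expression of 8 genes as log2(CPM + 0.1) (y axis) in each library (points), by ethanol concentration and hours (x axis), with a bar at the log2 of the group mean plus 0.1; time zero in black, 0% ethanol in blue, 5% ethanol in red. sodh-1 climbed to 2812 CPM in the 0% group at 20 h and stood at 62.4 CPM in 5% ethanol.

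After 20 h, among genes with at least 10 counts in each group and a mean of at least 5 CPM, the largest rises over the control were those of ugt-37 (9.05 ± 0.28), the fatty acid desaturase gene fat-5 (8.90 ± 0.37), the acyltransferase gene oac-14 (8.76 ± 0.40), cyp-35C1 (8.62 ± 0.30), C40H1.8 (7.99 ± 0.37) and gba-2 (7.92 ± 0.23). cyp-35C1 stood at 341.6 ± 103.6 CPM in ethanol (SD, n = 3). Under the same limits the genes lowest against the control were the collagen genes sqt-3 (-8.18 ± 0.61) and dpy-14 (-7.81 ± 0.55), the lipocalin genes lpr-3 (-7.96 ± 0.72) and lpr-4 (-7.78 ± 0.43), glf-1, which encodes UDP-galactopyranose mutase (-8.08 ± 0.63), and F13B12.4 (-8.80 ± 0.46). The largest adjusted p of these 12 genes was 1.54e-08. In all, 8142 genes differed, 3833 higher and 4309 lower in ethanol. The balance turned with library sizes alone (4295 higher, 3708 lower) and without ethanol replicate 3 (4200 and 3843). It was near even without the members of the embryo, cuticle, molting, hypodermis and muscle lists (4061 and 4056), an alternative chosen after seeing the data. The libraries of the 2 groups were separate for 55.4% of genes, where chance gives 10%. Of the genes called, 1215 had under 10 counts in a group, among them R05G9R.1, at least 249.2-fold lower. dpy-14 stood at 812 ± 109 CPM in the control and 3.68 ± 3.22 CPM in ethanol. At time zero it was at 0.170 ± 0.149 CPM (SD, n = 4).

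Molting genes were lower for 18 of 22 and higher for none at 20 h (18 adjusted over the list alone), with a median of -3.53 and adjusted p = 0.102 with an estimated correlation. The log2 fold change was -9.39 ± 0.95 for mlt-11 and -8.14 ± 0.61 for mlt-9. Cuticle collagen genes were lower for 77 and higher for 13 of 135 (79 and 15 adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). dpy-7 was at -8.85 ± 0.45 and dpy-3 at a ratio of ethanol to control counts of 0.00169 (0.000204 to 0.00612). Hypodermis and seam genes were lower for 11 and higher for 1 of 15 (11 and 1 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). The hedgehog-related genes wrt-2 and wrt-1 were at -8.38 ± 0.82 and -6.83 ± 0.50. Body wall muscle genes were lower for 16 of 17 (16 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). The troponin I gene tni-1 was at -4.02 ± 0.24 and the myosin gene myo-3 at -3.50 ± 0.35. In the same control libraries hch-1, a hatching protease gene of embryos, stood at 101 ± 15.0 CPM, against 0.134 ± 0.120 CPM in ethanol at 20 h and no counts at time zero.

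At 20 h FMRFamide-like neuropeptide genes were lower for 24 and higher for 1 of 30 (25 and 1 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). flp-25 was at -2.13 ± 0.28 and flp-6 at -1.88 ± 0.20. Neuronal markers were lower for 17 and higher for 2 of 22 (17 and 4 adjusted over the list alone; adjusted p = 0.695 with an estimated correlation). The synaptogyrin gene sng-1 was at -3.37 ± 0.31 and slo-1, a calcium-activated potassium channel gene, at -2.55 ± 0.38. Hypoxia response genes were lower for 8 of 9 (8 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation). Members lower included phy-2 (-3.74 ± 0.46), a collagen prolyl hydroxylase subunit, and sqrd-1 (-3.56 ± 0.19), a sulfide oxidase. At time zero (SD, n = 4), in the 20 h control and in ethanol (SD, n = 3), phy-2 was at 40.75 ± 5.59, 600.7 ± 219.2 and 45.06 ± 42.5 CPM. In that order sqrd-1 was at 18.74 ± 0.722, 28.91 ± 7.93 and 2.44 ± 0.269 CPM. Genes of the tricarboxylic acid and glyoxylate cycles and gluconeogenesis were lower for 16 and higher for 1 of 25 (18 and 1 adjusted over the list alone; adjusted p = 0.707 with an estimated correlation). pck-1 was at -3.79 ± 0.46 and the succinate dehydrogenase gene sdha-1 at -1.91 ± 0.22. In the same libraries early zygotic genes of the embryo were lower in ethanol for 26 and higher for 4 of 32. Genes of mid and late embryos were lower for 13 and higher for 1 of 19. With an estimated correlation these lists, chosen after seeing the data, had adjusted p = 0.018 and 0.00394, but over fewer tests than the other lists. Unadjusted, camera with an estimated correlation gave them p = 0.008 and 0.000875, the molting list 0.00241 and the spermatogenesis list 0.00666. Of the mid and late embryo genes, hch-1 was at 101 ± 15.0 CPM in the control and 0.134 ± 0.120 in ethanol (SD, n = 3). sodh-1 was lower in ethanol than in the control (-5.495 ± 0.221), at 62.4 ± 13.8 against 2812 ± 711 CPM (SD, n = 3), and had been at 37.8 ± 3.52 CPM at time zero (SD, n = 4). The aldehyde dehydrogenase gene alh-1 had a log2 fold change of -1.23 ± 0.16. acs-2 (-4.76 ± 0.44) and icl-1 (-1.58 ± 0.24) were lower in ethanol than in the control.

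Spermatogenesis genes were higher in ethanol for 50 of 53 and lower for none at 20 h (50 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation). ssp-34 was at 4.27 ± 0.25 and ssp-36 at a count ratio of 28.6 (4.78 to 1162). Both groups were lower than time zero for ssp-34 (-5.39 ± 0.25 in the control and -1.12 ± 0.18 in ethanol), which was at 30.15 ± 4.08 CPM at the start (SD, n = 4), 0.720 ± 0.296 in the 20 h control and 13.8 ± 1.95 in ethanol. UDP-glucuronosyltransferase genes were higher for 40 and lower for 9 of 62 (41 and 9 adjusted over the list alone; adjusted p = 0.462 with an estimated correlation). ugt-14 was at 8.18 ± 0.35 and ugt-25 at 7.37 ± 0.30. Cytochrome P450 genes were higher for 38 and lower for 12 of 65 (38 and 14 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). cyp-13A12 had a count ratio of 2264 (626.3 to 18700) and cyp-13A8 at least 270.3-fold higher. The unfolded protein response list had 12 of 21 members higher (12 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). ckb-2 was at 4.16 ± 0.22, pdi-6 at 2.26 ± 0.14 and hsp-4 at 1.96 ± 0.22. Histone genes were higher for 20 and lower for 2 of 29 (20 and 2 adjusted over the list alone; adjusted p = 0.462 with an estimated correlation). his-70 was at 2.75 ± 0.39 and his-57 at a count ratio of 69.2 (12.1 to 2768). Proteasome genes were higher for 14 of 32 (14 adjusted over the list alone; adjusted p = 0.707 with an estimated correlation). rpn-12 was at 0.98 ± 0.19 and pas-5 at 0.96 ± 0.20. Metal response genes were higher for 5 of 11 (5 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). mtl-2 was at 3.95 ± 0.27 and cdr-4 at 3.53 ± 0.36.

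At 20 h sod-3 was higher than in the control by 1.56 ± 0.23, at 4.23 ± 1.21 CPM in ethanol and 1.42 ± 0.204 in the control (SD, n = 3). At time zero it had been at 4.295 ± 0.520 CPM (SD, n = 4). At 20 h hsp-16.2 (0.11 ± 0.82), hsp-70 (-0.16 ± 0.83), hsp-6 (-0.14 ± 0.39), gst-4 (0.22 ± 0.28), gcs-1 (-0.36 ± 0.24), mtl-1 (0.59 ± 0.27) and fat-7 (0.13 ± 0.35) did not pass the test. gpdh-1 had a count ratio of 3.75 (1.03 to 20.5) and adjusted p = 0.0534. The value of hsp-70 rested on ethanol replicate 2, without which it was -3.05 (adjusted p = 0.0013), and hsp-16.2 was then -2.51 (0.00816). nlp-29 passed narrowly at -0.95 ± 0.40 (adjusted p = 0.0493). Its call ended with limma-voom (0.209), library sizes alone (0.123), RLE factors (0.0515), upper-quartile factors (0.0554), no low-count filter (0.0699) and only the 20 h libraries (0.214). It was -0.13 (0.795) without control replicate 1, -0.76 (0.179) without ethanol replicate 1 and -0.81 (0.149) without ethanol replicate 3. With the alternatives chosen later it was -0.07 (0.898) without the 6 libraries with scores above 10, -0.06 (0.903) without the library farthest from its group median, -0.96 (0.0503) with the length slope covariate and -0.93 (0.0545) without the embryo and cuticle genes. mtl-1 passed with limma-voom (0.0378), library sizes alone (0.0223), without control replicate 3 (0.0303) or without ethanol replicate 1 (0.0339). gpdh-1 passed with limma-voom (0.0197), library sizes alone (0.0324), without control replicate 1 (0.00214), ethanol replicate 1 (0.0436) or ethanol replicate 3 (0.0284). It also passed without the 6 libraries with scores above 10 (0.00244) and without the library farthest from its group median (0.00325). Its 3 counts in the 20 h controls were all in replicate 1, so where that library was left out the controls held 0 counts and no fold is given. With the length slope covariate gpdh-1 (0.0441), mtl-1 (0.00136) and gcs-1 (0.000982) passed, and gcs-1 also without the library farthest from its group median (0.0396). Without control replicate 1 the proteasome and neuronal lists missed the threshold (0.0585 and 0.0557), as the metal response list did without control replicate 2 (0.0524) or control replicate 3 (0.0506). Library sizes without composition factors shifted the median of all genes at 20 h by 0.16 on the log2 scale, and the metal response list then had adjusted p = 0.052, and 0.0835 with the length slope covariate.

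**Figure D3:**
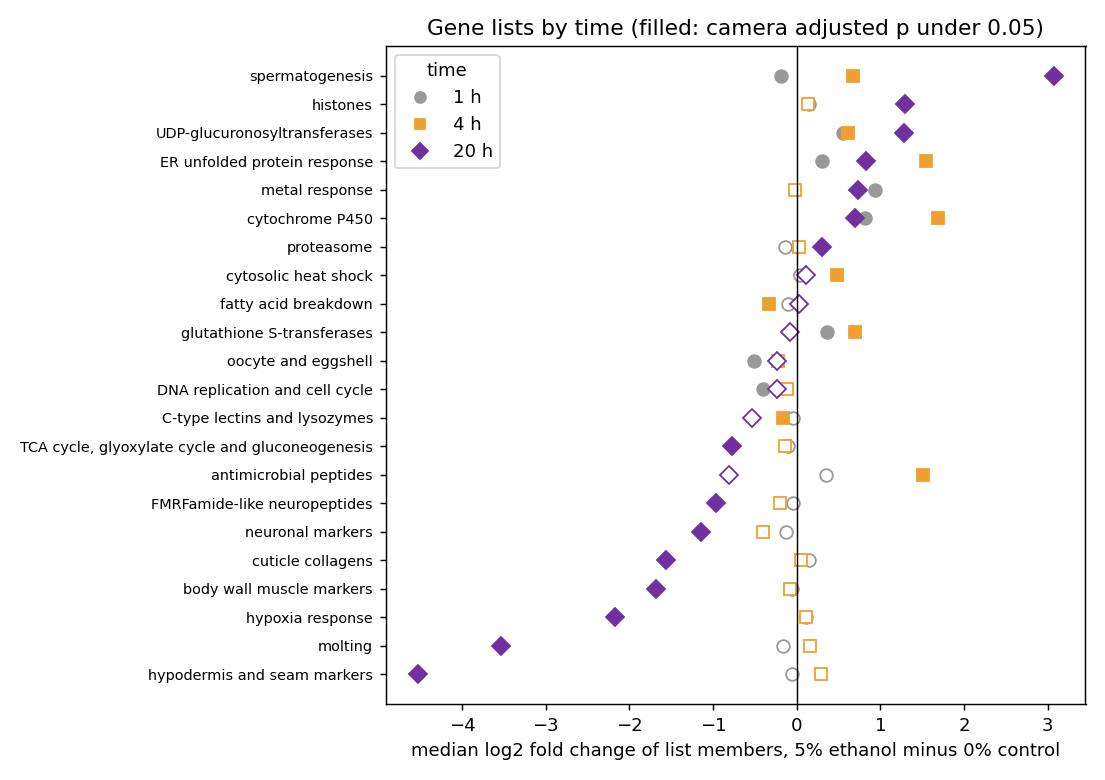
Median log2 fold change (x axis, 5% ethanol minus 0% ethanol) of the members of each gene list that passed camera's threshold at 1, 4 or 20 h (y axis), with filled symbols where it passed. Spermatogenesis stood at -0.19, 0.67 and 3.07 at 1, 4 and 20 h, and molting at -3.53 at 20 h.

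Several lists chosen for ethanol and stress did not pass camera's threshold at any time. With fry, the alcohol and aldehyde dehydrogenase list passed as lower at 4 h (adjusted p = 0.00377) and the osmolyte list as higher at 1 h (0.00991). Of 16 alcohol and aldehyde dehydrogenase genes, 1 was lower at 1 h, 3 were higher and 5 lower at 4 h, and 3 were higher and 9 lower at 20 h. The counts adjusted over the list alone were 2 higher and 1 lower, 3 and 5, and 3 and 9. The camera test gave adjusted p = 0.313, 0.313 and 0.116. Of 18 oxidative stress defence genes none was called at 1 h, 2 were higher and 4 lower at 4 h, and 4 were higher and 4 lower at 20 h. The counts adjusted over the list alone were 0 and 0, 2 and 4, and 4 and 3. The camera test gave adjusted p = 0.914, 0.662 and 0.999. Of 12 mitochondrial chaperone and protease genes 1 was higher at 1 h, none was called at 4 h, and 3 were higher and 1 lower at 20 h. The counts adjusted over the list alone were 1 and 0, 0 and 0, and 2 and 1. The camera test gave adjusted p = 0.646, 0.646 and 0.715. Of 20 osmolyte genes 4 were higher at 1 h, 6 higher and 5 lower at 4 h, and 4 higher and 9 lower at 20 h. The counts adjusted over the list alone were 5 and 0, 6 and 5, and 5 and 9. The camera test gave adjusted p = 0.131, 0.999 and 0.678. Of 76 cytosolic ribosomal protein genes none was called at 1 or 4 h, and 2 were higher and 9 lower at 20 h. The counts adjusted over the list alone were 0 and 0, 0 and 0, and 1 and 2. The camera test gave adjusted p = 0.26, 0.825 and 0.632.

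The ethanol effect itself differed between times for 6237 of the 15310 genes, by a test with 2 degrees of freedom. The 4 h effect differed from the 1 h effect for 2012 genes, the 20 h effect from the 4 h effect for 4952, and the 20 h effect from the 1 h effect for 5461. gpdh-1 was higher at 1 h and its effect fell by 3.83 ± 0.63 from 1 to 4 h, whereas the effect on hsp-4 was larger at 4 h than at 1 h by 2.27 ± 0.31. For acs-2 the effect relative to the control changed sign. The effect rose by 4.35 ± 0.56 from 1 to 4 h and fell by 7.48 ± 0.60 from 4 to 20 h. In the control acs-2 was at 233.4 ± 57.95, 6.22 ± 1.42 and 173.1 ± 97.9 CPM (SD) at 1, 4 and 20 h. In ethanol acs-2 was at 75.45 ± 12.82, 41.24 ± 3.76 and 6.45 ± 3.96 CPM (SD). The mean in ethanol thus fell at each step, while the control fell and rose again. Calls overlapped between times in both directions: 479 genes were higher at 1 and 4 h (129.2 for independent lists), and 62.9% of the 264 genes lower at 1 h were lower at 4 h (35.4 genes for independent lists). For 4 and 20 h 1726 were higher at both (653.9) and 1280 lower (577.5). For 1 and 20 h 443 genes were higher at both (189.5) and 133 lower (74.3). No library is shared between these comparisons. Fisher's exact test across genes, which are not independent replicates, gave its largest p for the 133 genes lower at 1 and 20 h, at 1.56e-14.

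In buffer without ethanol, transcript levels moved away from time zero as well, with 1657 genes called at 1 h (816 higher, 841 lower), 7068 at 4 h (3506 higher, 3562 lower) and 8442 at 20 h (4709 higher, 3733 lower). At 1 h higher calls made up 49.25%, and 39.98% with upper-quartile factors. With the length slope covariate, chosen after seeing the data, 2768 were higher and 1696 lower. Among genes with at least 10 counts in each group and a mean of at least 5 CPM, F26A1.8 (8.12 ± 0.30), C50F7.5 (5.10 ± 0.38), ugt-52 (4.54 ± 0.36) and F10C2.7 (4.46 ± 0.40) rose most at 1 h. At the same time F22F7.8 (-4.06 ± 0.34), F19B2.5 (-3.86 ± 0.67), ZK1290.5 (-3.38 ± 0.34) and ugt-63 (-3.35 ± 0.32) fell most. Under the same limits the largest rises at 4 h were those of mtl-1 (7.97 ± 0.37), F26A1.8 (7.51 ± 0.30), cyp-37B1 (6.45 ± 0.38) and scl-2 (6.06 ± 0.28). The largest falls were those of F18E3.11 (-7.25 ± 0.70), the saposin-like gene spp-23 (-6.85 ± 0.46), R193.2 (-6.61 ± 0.75) and F19B2.5 (-6.59 ± 0.82). Under these limits R09E10.5 (9.56 ± 0.50), the cuticlin gene cut-3 (9.42 ± 0.48), mtl-1 (9.13 ± 0.38) and clec-266 (9.01 ± 0.36) rose most at 20 h. The collagen genes col-149 (-10.01 ± 0.35) and col-133 (-8.17 ± 0.32) with ugt-63 (-7.47 ± 0.45) and F11E6.3 (-7.39 ± 0.48) fell most. The largest adjusted p of these genes was 0.000419, for F19B2.5 at 1 h. Called genes with under 10 counts in a group numbered 91, 534 and 1223, among them nspe-1 (at least 61.5-fold lower) and srh-2 (at least 57.3-fold higher) at 1 h. At 4 h they included T28A11.4 (at least 319-fold higher) and H43E16.1 (at least 207.9-fold lower). At 20 h they included col-74 (at least 2415-fold higher) and hch-1 (at least 1681-fold higher). In the 20 h control col-74 was at 147.4 ± 142.1 CPM and hch-1 at 100.9 ± 15.04 CPM (SD, n = 3), so the bound for col-74 rests on libraries that differed widely.

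Autophagy genes were higher in the control than at time zero for 10 of 26 at 1 h, 18 at 4 h and 17 at 20 h, with none lower (13, 19 and 17 adjusted over the list alone). With an estimated correlation the adjusted p was 0.00347 at 1 h, 0.00347 at 4 h and 0.0658 at 20 h. Spermatogenesis genes were lower in the control for 49 of 53 at 4 h and 52 at 20 h (50 and 52 adjusted over the list alone; adjusted p = 0.23 and 0.0658 with an estimated correlation). Fatty acid synthesis and desaturation genes were lower for 7 of 21 at 1 h, 13 at 4 h and 13 at 20 h, and higher for 0, 1 and 3 (the same counts adjusted over the list alone; adjusted p = 0.0334, 0.115 and 0.207 with an estimated correlation). Cuticle collagen genes were lower for 17, 79 and 83 of 135 and higher for 2, 5 and 29 (22, 85 and 84 lower adjusted over the list alone; adjusted p = 0.364, 0.246 and 0.337 with an estimated correlation). Molting genes were higher for 15 and lower for 2 of 22 at 20 h (15 and 3 adjusted over the list alone, adjusted p = 0.246 with an estimated correlation). Neuropeptide genes of the FMRFamide-like family were higher for 27 of 30 (29 adjusted over the list alone, 0.484). In the same libraries early zygotic genes of the embryo were higher for 25 and lower for 2 of 32 (0.018). Genes of mid and late embryos were higher for 16 and lower for 0 of 19 (0.00136). Both embryo lists were chosen after seeing the data and were adjusted over fewer tests than the other lists.

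Set against time zero, the ethanol groups had 1623 genes called at 1 h (1092 higher, 531 lower), 6002 at 4 h (3013 higher, 2989 lower) and 8119 at 20 h (4050 higher, 4069 lower). Higher calls made up 67.3% at 1 h by this test and 56.8% by DESeq2, and at 20 h 49.9%, against 62.6% with library sizes without composition factors. That scaling shifted the median of all genes by 0.25 on the log2 scale at 20 h and 0.12 at 4 h, and by 0.12 for the control against time zero at 4 h. Without ethanol replicate 3 the 531 lower calls at 1 h became 344, and the 1623 calls became 2470 without the 6 libraries with scores above 10 and 3482 without the library farthest from its group median. The 1657 calls for the control at 1 h became 5612 in the last. Genes called in the same direction from time zero in control and in ethanol numbered 460 higher and 314 lower at 1 h (58.2 and 29.2 for independent lists), 1726 and 1954 at 4 h (690 and 695.4), and 2200 and 2548 at 20 h (1246 and 992.1). Of the genes lower in ethanol than in the control, 48.1% at 1 h (127 genes, 6.14 for independent lists), 42.01% at 4 h (862, 238.6) and 50.9% at 20 h (2194, 706.2) were higher than time zero in the control and not in ethanol. Of those higher in ethanol, 47.03% (356 genes, 31.2 for independent lists), 35.4% (925, 219.6) and 32.2% (1235, 463.2) were higher than time zero in ethanol and not in the control. These comparisons share libraries, and choosing genes lower in ethanol than in the control favours genes high in the control, neither of which the numbers for independent lists take in. In 8 simulations of unchanged groups at most 1 gene was called in either list of a pair, so their overlap of 0 genes says nothing about these shares.

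Across genes, which are not independent replicates, the changes from time zero in the 2 treatments had Pearson's r of 0.569, 0.576 and 0.524 at 1, 4 and 20 h. Groups simulated without any change against the same 4 libraries gave 0.425, 0.438 and 0.441, and splitting those libraries gave means of 0.451, 0.537 and 0.506. The covariances were 0.220, 0.723 and 1.42, against simulated covariances of 0.0380, 0.0387 and 0.0389.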

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

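The tests of gene length, of oocyte content, of the spermatogenesis and DNA replication lists and of mislabelling were chosen after the scores of the libraries had been seen, and the count of regroupings that mixed all times after the other regroupings had been seen. At time zero 1 of 4 libraries lay far from the other 3 for ZK550.2 (replicate 2, 15.2 CPM, the others 13.03 to 13.4), alh-1 (replicate 1, 411.4 CPM, the others 347.4 to 355.1), glf-1 (replicate 2, 3.36 CPM, the others 1.35 to 1.49) and myo-3 (replicate 1, 182.6 CPM, the others 105.9 to 113.5). These were 4 of 112 tests, and chance gives about 1 in 20.

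The ethanol effect differed between times for 6237 genes, and for 76 of the 93 named genes by the test of the difference itself. For each of these the largest of the 3 pairwise differences follows, on the log2 scale. Fitted differences of genes with a group at 0 counts, such as F13B12.4, clec-28 and clec-25, depend on the prior count.

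The ethanol effect at 4 h exceeded that at 1 h for gba-2 (3.96), hsp-4 (2.27), cdr-4 (4.34), pdi-6 (2.63), ugt-33 (4.28), F08G2.5 (6.86) and ckb-2 (3.97). The effect at 4 h lay below that at 1 h for nhr-62 (-3.28), scl-2 (-1.66), gpdh-1 (-3.83), mtl-1 (-1.94), icl-1 (-1.60), ugt-10 (-3.40), C48B4.1 (-6.08) and F11F1.1 (-5.69). Also below its 1 h value at 4 h was the effect on clec-28 (-8.17) and clec-25 (-6.24).

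The ethanol effect at 20 h exceeded that at 4 h for ugt-8 (4.05), cyp-34A2 (4.79), cpt-4 (3.51), ech-9 (8.41), ugt-37 (5.64) and mtl-2 (4.42). The effect at 20 h lay below that at 4 h for pgp-1 (-2.77), hsp-70 (-4.73), gst-4 (-2.18), acs-2 (-7.48), nlp-29 (-4.35), fmo-2 (-7.11), lipl-6 (-7.98) and nlp-30 (-4.10). Also below its 4 h value at 20 h was the effect on F13B12.4 (-14.65), glf-1 (-8.95), lpr-3 (-8.26), mlt-11 (-9.92), mlt-9 (-8.70), dpy-3 (-7.998), dpy-7 (-9.08) and tni-1 (-5.50). Further negative differences between 20 h and 4 h were those of wrt-2 (-8.12), wrt-1 (-10.19), phy-2 (-4.48), pck-1 (-3.95) and sdha-1 (-1.77).

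The ethanol effect at 20 h exceeded that at 1 h for cyp-13A12 (5.65), ZK550.2 (7.01), thn-2 (3.08), math-24 (3.39), sod-3 (1.22), clec-210 (7.06), ssp-31 (3.85) and ugt-14 (5.23). Also larger at 20 h than at 1 h was the effect on cnc-2 (4.79), fat-5 (9.51), oac-14 (6.73), cyp-35C1 (5.94), C40H1.8 (6.70), ssp-36 (4.45), ssp-34 (4.37) and ugt-25 (3.64). Further positive differences between 20 h and 1 h were those of his-70 (2.35), rpn-12 (0.87) and pas-5 (0.99). The effect at 20 h lay below that at 1 h for sodh-1 (-4.48), alh-1 (-1.09), cdr-2 (-1.49), cyp-37B1 (-7.95), sqt-3 (-7.98), dpy-14 (-9.11), lpr-4 (-7.94) and myo-3 (-3.45). Also below its 1 h value at 20 h was the effect on flp-25 (-2.54), flp-6 (-1.54), sqrd-1 (-3.70), sng-1 (-3.23) and slo-1 (-2.39).

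Along the main axis of variation within groups, 6 of 22 libraries had scores above 10 and 8 lay as far on the other side, and no explanation from the study's groups was tested. Library size was argued against by Pearson's r of -0.175 between score and total over the 22 libraries (permutation p = 0.4376; Spearman's rho -0.251, permutation p = 0.2582; r -0.320 without the 2 libraries farthest from the median total). A wrong label was argued against by the genes separating group means, of which at least 92.35% lay nearer to the own group for each of the 22 libraries (lowest for control replicate 1 at 20 h), in a test that replaced, after its outcome was seen, one by overall closeness to the group means in which 1 of the 22 was nearer to another group. A bias by gene length may contribute, since the axis followed log2 exon length across genes, which are not independent replicates (r 0.4915, rho 0.525), and why it arose stays open. A difference in oocyte content between libraries may contribute as well: after the trend on length was taken out, 11 of the 15 oocyte and eggshell genes had loadings above 0, with a median at percentile 100 of 10000 random lists matched on mean expression, and lin-41, cbd-1 and cpg-1 had the highest loadings among genes of at least 50 CPM, though cpg-9 had the lowest, and the spermatogenesis and DNA replication lists also lay at percentile 100, so the test does not single out oocytes.

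For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Ethanol gave 1021 genes at 1 h (highest other split 3905, 2 of 10 as large), 4664 at 4 h (highest other 0, 1 of 10) and 8142 at 20 h (highest other 114, 1 of 10). The split with 3905 set ethanol replicates 1 and 3 and control replicate 1 against the rest, which points to a structure of the samples along the same axis. Lists called numbered 8 at 1 h (highest other 14, 6 of 10 splits as large), 9 at 4 h (highest other 9, 2 of 10) and 15 at 20 h (highest other 20, 3 of 10). For control against time zero at 1 h chance could not be excluded, with 1657 genes against 1833 for the highest other split, of control replicates 2 and 3 with time zero replicate 1 (2 of 35 as large). At 4 h (7068, highest other 3480) and 20 h (8442, highest other 5326) the real split gave the most genes. That is 1 of 35 splits as large, the smallest share possible, with no adjustment over the comparisons. For ethanol against time zero the real split also gave the most genes at 1 h (1623, highest other 698), 4 h (6002, highest other 2674) and 20 h (8119, highest other 4125), also 1 of 35. In these comparisons the highest other split set 3 time zero libraries against the rest, so it held part of the real difference. For the difference between times the regroupings decide nothing. Of 60 regroupings of the treatment within times 4, the real one included, gave as many as 6237 genes. The other 3 kept the real labels at 4 h with the labels at 20 h exchanged (11398 and 7985) or real (6460), so they held real effects, and exchanging 1 time builds a difference between times. Among the 40 that mixed the treatments at all 3 times the highest was 1640.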

How the results depend on the processing

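Leaving out the 6 libraries with scores above 10 or the library farthest from its group median, the length slope covariate and the fit without embryo and cuticle genes were chosen after seeing the data. Of 616 counts recomputed for 37 results, 552 lay within 1.5 times the reported count and 64 did not. Of 163 results for named genes, 136 kept their call and direction in every alternative in which they were tested and 27 did not. The minimum log2 fold change was not applied to named genes. An alternative that dropped a gene was not counted against it. Lists were rerun with library sizes alone, the replicate block, libraries left out, the length slope covariate, an estimated correlation and fry. Of 32 list calls 1 held in all of these, 31 ended with an estimated correlation and 10 ended in at least 1 other. Without leaving libraries out, the alternatives fixed in advance gave 620 to 1119 genes for ethanol at 1 h, 2997 to 6515 at 4 h and 5630 to 8493 at 20 h. Except where an alternative's construction shows it (fewer genes pass a size threshold, fewer libraries enter a fit), the cause was not tested.

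With only the groups compared, ethanol gave 620 genes at 1 h (470 higher, 150 lower), 6515 at 4 h and 6045 at 20 h. Control against time zero then gave 1584, 8063 and 7121, so in both the order of 4 and 20 h turned. With library sizes alone, ethanol at 1 h gave 175 lower. Without the 6 libraries with scores above 10 it gave 1550 (523 lower), and ethanol against time zero at 1 h 2470 (958 lower), where DESeq2 gave 803 lower. Without the library farthest from its group median, ethanol gave 6715 genes at 1 h (3187 higher, 3528 lower), control against time zero at 1 h 5612 (3537 higher, 2075 lower), ethanol against time zero at 1 h 3482 (2068 higher, 1414 lower) and the difference between times 9937. The length slope covariate was estimated from the same data and took out spread within groups alone. Ethanol then gave 3578 genes at 1 h (1669 higher, 1909 lower) and 7296 at 4 h (3515 lower). With it, control against time zero gave 4464 at 1 h (2768 higher, 1696 lower), ethanol against time zero 3832 at 1 h (2346 higher, 1486 lower) and 9483 at 4 h (4630 higher, 4853 lower), and the difference between times 10492. With an absolute log2 fold change of at least 1, ethanol gave 154 lower at 1 h, 2997 at 4 h (1706 higher, 1291 lower) and 2524 higher at 20 h. Control against time zero then gave 975 at 1 h (468 higher, 507 lower) and 4037 at 4 h (1406 higher), and ethanol against time zero 994 at 1 h (248 lower), 3503 at 4 h (1618 higher, 1885 lower) and 4999 at 20 h (2115 higher). The overlaps were then 96 lower for 1 and 4 h, 1039 higher and 801 lower for 4 and 20 h, and 61 lower for 1 and 20 h. With each library left out in turn, lower calls ran from 153 to 241 for ethanol at 1 h (171 without control replicate 2, 165 without control replicate 3) and from 344 to 517 for ethanol against time zero at 1 h. An estimated correlation left 1 list at 1 h, 0 at 4 h and 0 at 20 h, and fry called 15 at 4 h and 25 at 20 h.

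The replicate number did not pair the libraries at every time: 3 of 9 same-numbered pairs had a correlation above 0.1 (from -0.360 to 0.621) and 2 of 9 correlated best with their own number. Both of the latter were at 1 h, replicate 1 (r 0.603) and replicate 2 (0.621), where replicate 3 had -0.0685. A pairing of these 1 h libraries therefore stays possible. With the replicate block, ethanol gave 844, 4322 and 7717 genes at 1, 4 and 20 h and the calls of spe-42, dnj-19 and nlp-29 (20 h) ended. At these depths and this spread between libraries, which were not varied separately, a simulated fold change of 1.5 was recovered for 5.97% of changed genes at 1 h, 2.99% at 4 h and 8.96% at 20 h. The simulation changed far fewer genes than were called in the real libraries, so these shares also depend on that setting.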

Other observations

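The embryo gene lists, the tests on them and the comparison of the tissue lists with time zero were chosen after the 20 h results had been seen. Adjusted p values of the embryo lists took in fewer tests than those of the other lists. At time zero, transcripts of genes known from adult hermaphrodites were abundant although the labels name larval stages: vit-6, a yolk protein gene, stood at 18480 ± 3515 CPM (SD, n = 4) and the eggshell genes cpg-1 and cbd-1 at 918 ± 601 and 1353 ± 954 CPM. Insulin pathway targets were higher in the control than at time zero for 8 and lower for 1 of 10 at 20 h (8 and 1 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation). Glycolysis genes were lower in the control for 12 of 16 at 4 h (12 adjusted over the list alone; adjusted p = 0.547 with an estimated correlation).

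Early zygotic genes of the embryo were higher in the control than at time zero for 26 of 32 at 4 h and 25 at 20 h, and lower for 1 and 2 (adjusted p = 0.00394 and 0.018 with an estimated correlation). In ethanol they were lower than in the control for 25 at 4 h and 26 at 20 h, and higher for 2 and 4 (0.00295 and 0.018). pes-10 stood at 5.91 ± 0.739 CPM in the 4 h control and 0.176 ± 0.0900 CPM in ethanol (SD, n = 3). Genes of mid and late embryos were higher in the control than at time zero for 16 of 19 at 20 h (0.00136) and lower in ethanol than in the control for 13, with 1 higher (0.00394). At 1 h 5 of them were higher in ethanol (0.00534), and at 4 h 8 were higher and 1 lower (0.0799).

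At 20 h 122 of 189 genes of the cuticle, molting, hypodermis and body wall muscle lists were lower in ethanol, with a median log2 fold change of -1.85 (8117 genes were called in all without these and the embryo genes). Scaling of the libraries was argued against by the median with library sizes alone (-1.70, the weakest of 3 other scalings), and gene length by the median after a length trend was taken out (-1.58, from -1.84 for the 186 members with a length). A candidate explanation that stays open is RNA of embryos or hatched larvae in the 20 h control libraries: the 51 embryo genes, 3 of which are in another list, had a median of -3.19 for ethanol minus control, 2.98 for control minus time zero and 0.30 for ethanol minus time zero. The body wall muscle list did not gain in the control (median -0.03 against time zero, 4 of 17 higher, myo-3 among them, and 6 lower) and lay below time zero in ethanol (median -1.74, 14 lower and 1 higher; adjusted p = 0.23 with an estimated correlation), so for these genes embryo RNA would have had to make up for a fall in the control. An effect of ethanol on the treated worms themselves also stays open, with tni-1 at 81.2 ± 13.7 CPM at time zero (SD, n = 4), 77.5 ± 7.83 in the 20 h control and 4.79 ± 1.01 in ethanol (SD, n = 3) and the adult collagen gene col-19 at 2062.6 ± 300.6, 1066 ± 177 and 113 ± 53.5, but ethanol against time zero also holds 20 h in buffer, over which cuticle collagens fell in the control (median -1.83, and -3.44 in ethanol).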
